A study of Mus musculus with 6 samples.

How the data were processed

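The study sequenced RNA of the mouse nucleus accumbens at 24 h of withdrawal from repeated cocaine or saline, with 3 pools per group and 5 mice per pool. Groups were taken from the sample titles. Per the labels, cage mates all received the same treatment. The pools are separate sets of mice.

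CASAVA, TopHat and Cuffdiff, with the mouse builds mm9 and NCBIM37, are named per the submitters' processing notes; their versions, parameters, read numbers and annotation are not given in the sources used here. A single table was used, and per the file headers it compares a saline with a cocaine column in the layout of a Cuffdiff gene test. It gave 1 FPKM value per gene and group as deposited by the authors, who normalised to transcript length and mapped fragments. The header does not print the unit, which is taken from that layout. The authors' deposited p-value and the deposited q-value and test statistic, which are treated as a score because q is not limited to 1, were used as they stand, except for the sign of the statistic. In 100% of the status OK rows with unequal values above 0 in both groups, it was opposite to that of the log2 ratio of cocaine over saline. The sign was therefore turned where the statistic replaced the log2 ratio. All directions rest on the group names printed for the columns. The deposited p-value equals the two-sided normal p of the deposited test statistic to within a relative 9.29e-05. The authors marked genes at a q under 0.1. How many pools entered that test is not stated in the table, which gives no values per pool. Of 35406 rows, 23479 had status OK, 11655 NOTEST, 67 LOWDATA and 205 FAIL. The 205 FAIL rows are all listed at 0 in both groups, so a value of 0 there is a failed estimate. The FPKM values sum to 494406 for saline and 519872 for cocaine.

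The number of fragments per library could not be recovered: of 1700 NOTEST rows with 1 group at 0, the squared normal quantile of p was within 0.01 of a whole number in 47.9%. Depth is therefore unknown, no counting intervals are given for expression values, and tests for read counts were not run. The precision of each ratio is the implied standard error, the absolute log2 ratio divided by the absolute test statistic.

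Log2 ratios of cocaine over saline FPKM were computed without a pseudocount for genes above 0 in both groups, and no fold is given where a group is listed at 0. Genes were called at a q under 0.05 with status OK. The planned test on replicate values was not possible, and the authors' own test took its place, as laid down for that case. Start positions were written 1-based: 21 of 21 mitochondrial genes alone in their locus matched the reference annotation after adding 1 to the start in the table. A locus is the interval printed for a row, and 48.8% of the status OK rows had another row in theirs.

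The thresholds, the named-gene rule, the 31 gene lists with their tests, and the alternatives not stated as added later were set before the data were examined. Named genes were the 12 highest and 12 lowest called log2 ratios with at least 1 FPKM in both groups, the 3 highest and 3 lowest called below that, up to 4 called and 3 abundant uncalled members per list, and 11 genes fixed by name. Gene models without a symbol, pseudogenes and rows naming several genes were passed over. A further 8 list members (Arc, Atp5c1, Cacna2d1, Ehmt2, Hsph1, Npas2, mt-Co2 and mt-Nd5), which complete small counts, were chosen after their values were seen, as were Tardbp, Wdr55, Ino80e, Hirip3 and Ercc2. Some called list members that met the rule are not reported here.

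Lists were tested on 14193 genes with a single symbol, status OK, a mean of at least 1 FPKM and values above 0 in both groups, with 1 row per symbol. A list's median log2 ratio was placed among 10000 random lists with the same number of genes from each of 20 FPKM bins, two-sided, with Benjamini-Hochberg adjustment over the 31 lists. Called members were compared with all other genes by Fisher's exact test, two-sided, adjusted in the same way. The authors' p was also adjusted over each list alone. After the data were seen, random lists were matched on transcript length (10 bins), GC content (5 bins) and FPKM (4 bins). Length and GC content came from the longest GENCODE vM21 transcript of each symbol, and 96.2% of the genes had one; older symbols were looked up as RefSeq synonyms. A second version used the median protein-coding transcript length (20 bins, with 3 FPKM bins). Coordinates were not taken from that reference, which is of another build.

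Alternatives laid down beforehand were a q under 0.01 or 0.1, recomputed adjustment, other FPKM minimums, at least 1.5-fold, 1 row per symbol, a pseudocount of 1, centring on the median of all genes, the test statistic and the mean in place of the median. Added after seeing the data were rows alone in their locus, genes above 0 in both groups and the matching on length and GC content. The steps were tested on simulated data over the 14193 genes of the cocaine and saline comparison with their implied standard errors. Of 100 genes changed by 1.5-fold 57% were recovered, and of 100 changed by 2-fold 87%, all in the right direction, with 11 false calls among 155. The noise was drawn from the same implied standard errors that the simulated test used. These rates therefore follow from those errors and do not show how the calls fare if pools spread more. In 20 simulations with no shift, ratios divided by their implied standard errors were shuffled over genes and rescaled by each gene's own error. There 0 of 620 list tests passed after adjustment. These simulations used fewer random lists than the main test, too few for a list to pass the adjustment on its own. The 0 was thus nearly fixed in advance and does not measure how often lists pass falsely. The ribosomal protein, oxidative phosphorylation and potassium channel lists were found in 20 of 20 when shifted by 0.25, at an unadjusted p under 0.05. Shuffling removes the trend with transcript length and the correlation between genes. The simulations therefore do not show how often lists would pass in the real data without an effect. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.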

Results

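RNA sequencing was carried out on the nucleus accumbens, the part of the ventral striatum that receives dense dopamine input and is a main site of cocaine action, from male C57BL/6 mice aged 11 weeks. The mice had received repeated intraperitoneal injections of saline or of cocaine at 20 mg/kg over 1 week and were examined at 24 h of withdrawal. Each group had 3 pools, and each pool combined tissue of 5 mice from both hemispheres, so that 15 mice stood behind each group. The deposited table gave 1 expression value per gene for each group, in FPKM (fragments scaled to transcript length and to the number of mapped fragments), with no value per pool, and whether the authors' own test took in the spread between pools is not stated. It did not give the number of fragments per library, and the depth is unknown. All errors printed with a log2 ratio are the standard errors implied by the authors' test statistic, and need not hold that spread.

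The comparison of cocaine with saline asked which accumbens transcripts differed after a day without the drug. Transthyretin (Ttr), a thyroid hormone carrier made mainly by the choroid plexus, fell from 93.4 to 9.46 FPKM, a log2 ratio of -3.30 ± 0.16, in the authors' deposited table. Genes of mitochondrial respiration and of the ribosome were mostly higher: 70 of 76 nuclear-encoded oxidative phosphorylation genes were higher (36 called) and 66 of 72 cytosolic ribosomal protein genes (22 called). Their median log2 ratios were 0.27 and 0.26, and random lists matched on transcript length and GC content already had medians of 0.14. Against such lists, which were matched on FPKM too, the number of ribosomal calls did not pass after adjustment. Of 53 voltage-gated ion channel genes 35 were lower, with 9 of 24 potassium channel genes and 7 of 29 calcium and sodium channel genes called lower. Neither channel list passed after adjustment against genes matched on transcript length and GC content. The 53 genes together lay at percentile 4.85 with the longest transcript matched and at 0.99 with the median protein-coding transcript. NMDA receptor subunit Grin2b, in a locus shared with other rows, fell from 13.2 to 5.94 FPKM and Grin2a from 8.21 to 4.59 FPKM in the authors' deposited table. Of 22 glutamate receptor genes 3 were called (13.6%), against 14.6% of all genes used for the list tests. The median of that list lay at percentile 49.7 with transcript length and GC content matched. The transcription factors Fos and Fosb, the opioid precursor genes Pdyn and Penk and the dopamine receptor genes Drd1a and Drd2 were not called. Of these, Pdyn was near the threshold (q = 0.0529) and the log2 ratio of Penk had a large implied error (0.16 ± 0.59) in the authors' deposited table.

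At an authors' q under 0.05 among genes with test status OK, 2784 of 23479 genes (11.9%) were called, 1432 higher and 1352 lower after cocaine. The 23479 include 3425 genes at 0 in a group, of which 1000 were at 0 in exactly 1 group. The rest of these were at 0 in both groups and were not called, which lowers the share of 11.9%. The share higher was 51.4% (exact 95% interval 49.6 to 53.3). Most changes were small: the median absolute log2 ratio of the called genes above 0 in both groups was 0.50, a 1.42-fold difference. Among called genes with at least 1 FPKM in both groups, 1064 rose and 1035 fell, 602 differed by at least 1.5-fold and 112 by at least 2-fold (71 higher, 41 lower). The authors' own marking used a q under 0.1 and held 3436 genes. Limiting the calls to rows alone in their locus left 1183 genes, 55.6% of them higher, and 401 called genes were listed at 0 FPKM in one of the groups. The locus of the other 1601 called genes (57.5%) held another row. Below, a shared locus is stated for some genes only, and further named list members shared one too, among them Caln1, Grm5, Slc1a2 and Mef2d.

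Among the called genes with at least 1 FPKM in both groups, the deepest falls after Ttr (locus at chromosome 18, 20716575 to 20832825, in the mouse build the submitters' notes call mm9 and NCBIM37) were found in Masp2, a serine protease of the complement lectin pathway, and Dnd1, an RNA-binding protein of germ cells. Masp2 (chromosome 4, 147976663 to 148001128) fell from 8.14 to 1.45 FPKM with a log2 ratio of -2.49 ± 0.31 in the authors' deposited table, and Dnd1 (chromosome 18, 36919893 to 36925868) had a log2 ratio of -1.78 ± 0.24. Both shared their locus with a gene that was higher after cocaine in the authors' deposited table, Tardbp (log2 ratio 0.83) for Masp2 and Wdr55 (1.09) for Dnd1. Of the genes alone in their locus, the collagen-like Emid2 (-1.67), Phf21b (-1.41), the ubiquitin ligase Cbl (-1.34) and the Wnt coactivator Bcl9 (-1.26) had the lowest log2 ratios in the authors' deposited table. Cbl went from 15.6 to 6.13 FPKM and Bcl9 from 19.0 to 7.94 FPKM in the authors' deposited table. The rest of the 12 lowest were Ston2, an endocytic adaptor (-1.63), Ccdc17 (-1.32), the diacylglycerol kinase Dgkh (-1.24), Dlec1 (-1.22) and the mitochondrial transfer RNA mt-Te (-1.18), by the log2 ratios of the authors' deposited table.

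The highest ratios belonged in part to the mitochondrial genome, with the transfer RNA genes mt-Ts1 (2.28), mt-Tm (1.80) and mt-Tl1 (1.62) and the complex I gene mt-Nd3 (1.46) among the 12 highest log2 ratios of the authors' deposited table. Of these, mt-Ts1 shared its locus with the protein-coding gene mt-Co1. The 12 measured transfer RNA genes of the mitochondrial genome had a median length of 69 nt. Whether values scaled to transcript length hold for rows that short was not examined. Doc2a, a calcium-binding protein of synaptic vesicles (chromosome 7, 133990930 to 134008891), rose from 3.79 to 15.0 FPKM, a log2 ratio of 1.98 ± 0.24, in the authors' deposited table. Ino80e, in the same locus, fell from 37.5 to 25.9 FPKM and Hirip3, also in that locus, rose from 67.2 to 94.5 FPKM in the authors' deposited table, and the row of Ercc2 in the locus of Klc3 fell as well. Pemt, which methylates phosphatidylethanolamine to phosphatidylcholine (chromosome 11, 59784116 to 59859991), rose from 1.35 to 4.30 FPKM with a log2 ratio of 1.67 ± 0.39 in the authors' deposited table. The proteasome gene Psma3 rose from 16.5 to 50.5 FPKM, and Fam166a (1.60), Chic2 (1.57), the kinesin light chain gene Klc3 (2.04 to 5.78 FPKM), the caveolin gene Cav2 (1.42) and the small RNA row mmu-mir-2132.1 (1.99) completed the 12 highest log2 ratios of the authors' deposited table. Among called genes under 1 FPKM in a group, Acpt (4.50), Cdc6 (4.23) and Klk8 (3.98) had the highest and Esrp2 (-5.18), Gcnt7 (-4.66) and U1.17 (-4.57) the lowest log2 ratios in the authors' deposited table. Of the 24 genes named as highest or lowest at 1 FPKM or more, 13 shared a locus with another row, where fragments may have been divided between rows. Whether the transcripts of these genes overlap was not examined.

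**Figure D1:**
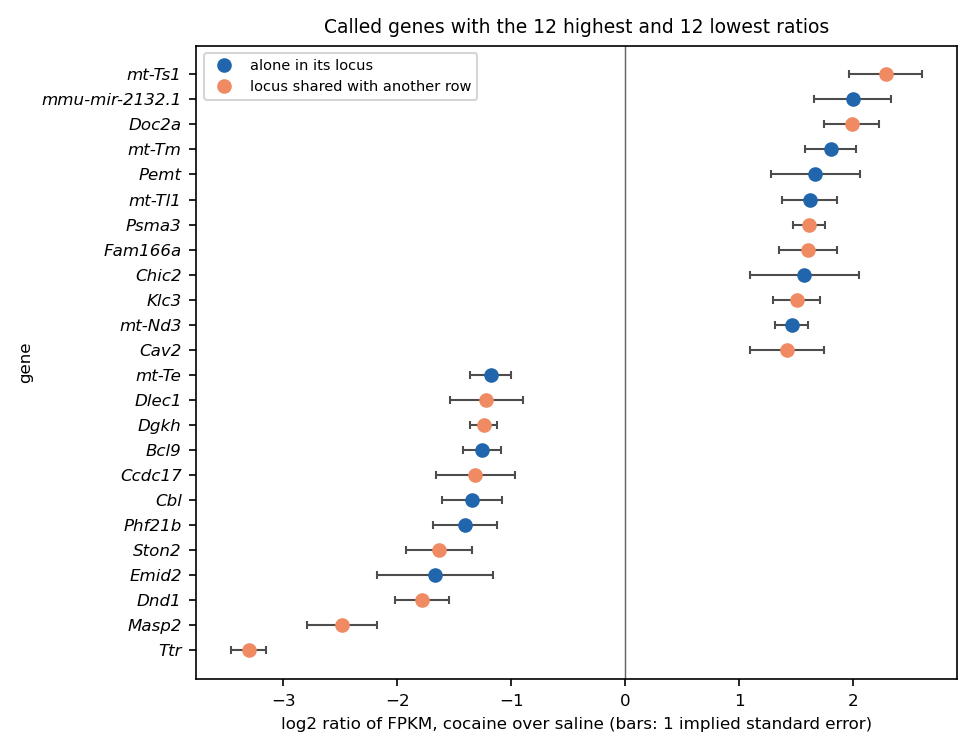
Log2 ratio of FPKM (cocaine over saline) for the 24 called genes with the 12 highest and 12 lowest ratios at 1 FPKM or more in both groups. Points are the ratios in the authors' deposited table, bars are 1 implied standard error, and colour marks whether the gene was alone in its locus (11 genes) or shared it (13 genes). Ttr lies lowest at -3.30 and mt-Ts1 highest at 2.28.

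Of 31 gene lists fixed before the data were examined, 6 had a median log2 ratio apart from 10000 random lists matched on FPKM after Benjamini-Hochberg adjustment. This describes how genes fell in a single pair of group values, and genes are not independent replicates. Across the 14193 genes used for the list tests, 14.6% were called. The nuclear-encoded oxidative phosphorylation genes had a median of 0.27 (percentile 100). Of the 76 measured, 37 were called (43 when adjusted over the list alone), 36 of them higher, and the odds of a call were 5.61 times those of other genes (Fisher's exact test, two-sided, adjusted p = 5.83e-11). Complex I genes Ndufc1 (1.36 ± 0.19) and Ndufa5 (0.70 ± 0.10), complex III gene Uqcrb (0.77 ± 0.20) and ATP synthase gene Atp5e (0.63 ± 0.13) led the called members by log2 ratio in the authors' deposited table, and the ATP synthase gene Atp5c1 was the single called member to fall (-0.29). The abundant Atp5a1 (0.06), Cox6a1 (-0.02) and Cox8a (0.21) were not called in the authors' deposited table.

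The 72 cytosolic ribosomal protein genes had a median log2 ratio of 0.26 (percentile 100), and 22 were called (24 when adjusted over the list alone), all 22 higher. Their odds of a call were 2.58 times those of other genes (Fisher's exact test, adjusted p = 0.0060). Rpl31 (0.66 ± 0.16), Rps13 (0.64 ± 0.17), Rps20 (0.62 ± 0.13) and Rpl9 (0.61 ± 0.16) had the largest called log2 ratios in the authors' deposited table, whereas Rplp1, at 520.4 and 591.8 FPKM, was not called. All 6 protein-coding genes of the mitochondrial genome that were measured were called (6 when adjusted over the list alone), with a median of 0.46. In the authors' deposited table, mt-Nd3, mt-Cytb (0.61), mt-Nd6 (0.61), mt-Co1 (0.31) and mt-Co2 (0.24) rose and mt-Nd5 fell by 0.12 on the log2 scale. Of these, mt-Nd5 and mt-Nd6 shared a locus, and mt-Co1 shared one with mt-Ts1. Implied standard errors were 0.0035 for mt-Co1, 0.0059 for mt-Cytb, 0.0065 for mt-Co2 and 0.0070 for mt-Nd5. Errors that small let even a fall of 0.12 be called, and need not hold the spread between pools. Those of mt-Nd3 (0.15) and mt-Nd6 (0.22) were larger. When random lists were also matched on transcript length and GC content, an alternative chosen after the data were seen, the oxidative phosphorylation and ribosomal lists still lay at percentiles 100 and 99.98, and the mitochondrial genome list at 81.6. Against such lists, which were matched on FPKM too, the excess of calls held for the oxidative phosphorylation genes (37 calls against a median of 16). It did not pass after adjustment for the ribosomal protein genes (22 against 14) or the mitochondrial genome (6 against 3). Fisher's exact test was not matched on FPKM, and the share of genes called rose with FPKM. Which of length, GC content and FPKM took up the excess was not tested.

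The 24 potassium channel genes had a median log2 ratio of -0.15 (percentile 0.42), and 9 were called, all 9 lower (10 when adjusted over the list alone). Kcnq3 fell from 12.5 to 6.34 FPKM, a log2 ratio of -0.98 ± 0.14, and Kcna2 (-0.91), Kcnd3 (-0.82) and Kcng3 (-0.65) followed in the authors' deposited table. The 29 calcium and sodium channel genes had a median of -0.16 (percentile 0.04), and 8 were called (9 when adjusted over the list alone). For rows alone in their locus the median was -0.08 and did not pass. In the authors' deposited table, the calcium channel genes Cacna1e (-0.65), Cacna1c (-0.59), Cacna2d2 (-0.43) and Cacna1b (-0.42) fell, and Cacna2d1 (0.41) was the single called member to rise. Of these, Cacna1e alone did not share its locus with another row. With matching on transcript length and GC content as well, the channel lists lay at percentiles 23.6 and 7.35, and neither passed after adjustment. Of the channel lists, the potassium channels held more calls than other genes (odds ratio 3.51, Fisher's exact test, adjusted p = 0.038). Against lists matched on length, GC content and FPKM this excess (9 calls, against a median of 5) did not pass, and which of these took it up was not tested.

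Of 22 glutamate receptor genes, 3 were called and all 3 fell (3 when adjusted over the list alone): Grin2b (-1.15 ± 0.12), Grin2a (-0.84 ± 0.14) and the metabotropic receptor gene Grm5 (-0.51 ± 0.09), by log2 ratio in the authors' deposited table. The AMPA receptor genes Gria1 (-0.14) and Gria2 (0.08) were not called in the authors' deposited table, and the list median of -0.10 lay at percentile 3.01, short of the threshold, which the list passed with the mean (-0.19) or the test statistic. With matching on length and GC content it lay at percentile 49.7, and the random lists had a median of -0.10 themselves. Of 18 genes of GABA receptors, synthesis and transport, 4 were called (4 when adjusted over the list alone). In the authors' deposited table Gabra4 (0.42) rose and Gabrb1 (-0.59) fell, with Gad1 (0.13) not called.

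Of 14 genes of dopamine synthesis, transport, receptors and signalling, 1 was called (3 when adjusted over the list alone): the receptor gene Drd3 fell from 6.06 to 3.88 FPKM in the authors' deposited table (log2 ratio -0.64 ± 0.20, q = 0.011). Drd1a went from 59.1 to 64.8 FPKM (q = 0.573) and Drd2 from 118 to 109.6 FPKM (q = 0.641) in the authors' deposited table. Among the 12 neuropeptide and opioid receptor genes, 3 were called (4 when adjusted over the list alone), and all 3 rose: Cck (0.46), the nociceptin receptor gene Oprl1 (0.44) and Tac1 (0.32), in the authors' deposited table. Pdyn, at 151 and 179 FPKM, missed the threshold (q = 0.0529), and Penk (0.16 ± 0.59) and Cartpt (-0.17 ± 0.12) were not called in the authors' deposited table.

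Of 22 immediate early genes, which neuronal activity induces within minutes, 5 were called (6 when adjusted over the list alone). Egr4 (0.46), Nr4a3 (0.45) and Jund (0.40) rose and Egr3 (-0.50) and Arc (-0.28) fell in the authors' deposited table. Fosb (0.35 ± 0.18, q = 0.244) and Fos (-0.35 ± 0.19, q = 0.256) were not called in the authors' deposited table. The list median of 0.21 lay at percentile 99.1, short of the threshold after adjustment. It lay at percentile 100 with matching on length and GC content, but the mean was 0.11 and the median with a minimum of 5 FPKM was 0.13, both short of the threshold. Of 29 genes tied to cocaine in earlier rodent work, 10 were called (13 when adjusted over the list alone), 9 of them lower, with odds of a call 3.08 times those of other genes (Fisher's exact test, adjusted p = 0.038). Against lists matched on length, GC content and FPKM, with a median of 7 calls, the excess did not pass. In the authors' deposited table the transcription factor genes Mef2d (-0.63 ± 0.07) and Creb1 (-0.61 ± 0.17) and the deacetylase gene Sirt2 (-0.43 ± 0.08) fell, and the histone methyltransferase gene Ehmt2 rose (0.17). Auts2, at 131913205 to 133019214 on chromosome 5, and Caln1, at 130845346 to 131316515 on the same chromosome, both fell, from 31.7 to 25.5 FPKM (log2 ratio -0.32 ± 0.10, q = 0.017) and from 55.4 to 43.4 FPKM (-0.35 ± 0.08, q = 0.00052), in the authors' deposited table. Bdnf was near 0.24 FPKM in both groups and Cdk5 went from 46.6 to 49.0 FPKM, neither called in the authors' deposited table.

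The 36 chromatin modifiers and organisers had a median log2 ratio of -0.10 (percentile 0.42), and 9 were called (10 when adjusted over the list alone), 7 of them lower. The DNA demethylase gene Tet2 (-0.54), the acetyltransferase genes Ep300 (-0.51) and Crebbp (-0.50) fell and the deacetylase gene Hdac2 (0.43) rose in the authors' deposited table. This list lay at percentile 21.3 once length and GC content were matched too. Of 29 replication-dependent histone genes, 0 were called (0 when adjusted over the list alone). Of 16 circadian clock genes, 6 were called (11 when adjusted over the list alone), with Hlf (-0.57), Clock (-0.35), Nr1d1 (-0.32), Npas2 (-0.32) and Per1 (-0.30) lower and Rorb (0.80) higher in the authors' deposited table. The clock list did not pass for its median (-0.07, percentile 9.56) or its calls (Fisher's exact test, adjusted p = 0.093). Its median was 0.07 for rows alone in their locus. Of 16 glucocorticoid-responsive genes, 4 were called (5 when adjusted over the list alone). Map3k6 (1.35), the lipid droplet gene Plin4 (1.26) and Tsc22d3 (0.51) rose, Per1 fell, and Sgk1 (0.28) was not called in the authors' deposited table. Of 15 chaperone and unfolded protein response genes, 5 were called (6 when adjusted over the list alone), and all 5 rose. In the authors' deposited table these were the heat shock genes Hspa1b (0.94 ± 0.22), Hspa1a (0.91 ± 0.21) and Hsph1 (0.24) and the endoplasmic reticulum genes Hspa5 (0.36 ± 0.07) and Manf (0.35). The medians of the glucocorticoid and chaperone lists, 0.27 and 0.24, lay at percentiles 99.2 and 98.9 and did not pass after adjustment. Both lists passed on FPKM + 1, with the test statistic in place of the log2 ratio, and with matching on length and GC content (percentiles 99.9 and 99.5), but not with the mean in place of the median, a minimum of 0.1 or 5 FPKM, or rows alone in their locus. The 5 interferon-responsive genes held 0 calls (0 when adjusted over the list alone).

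**Figure D2:**
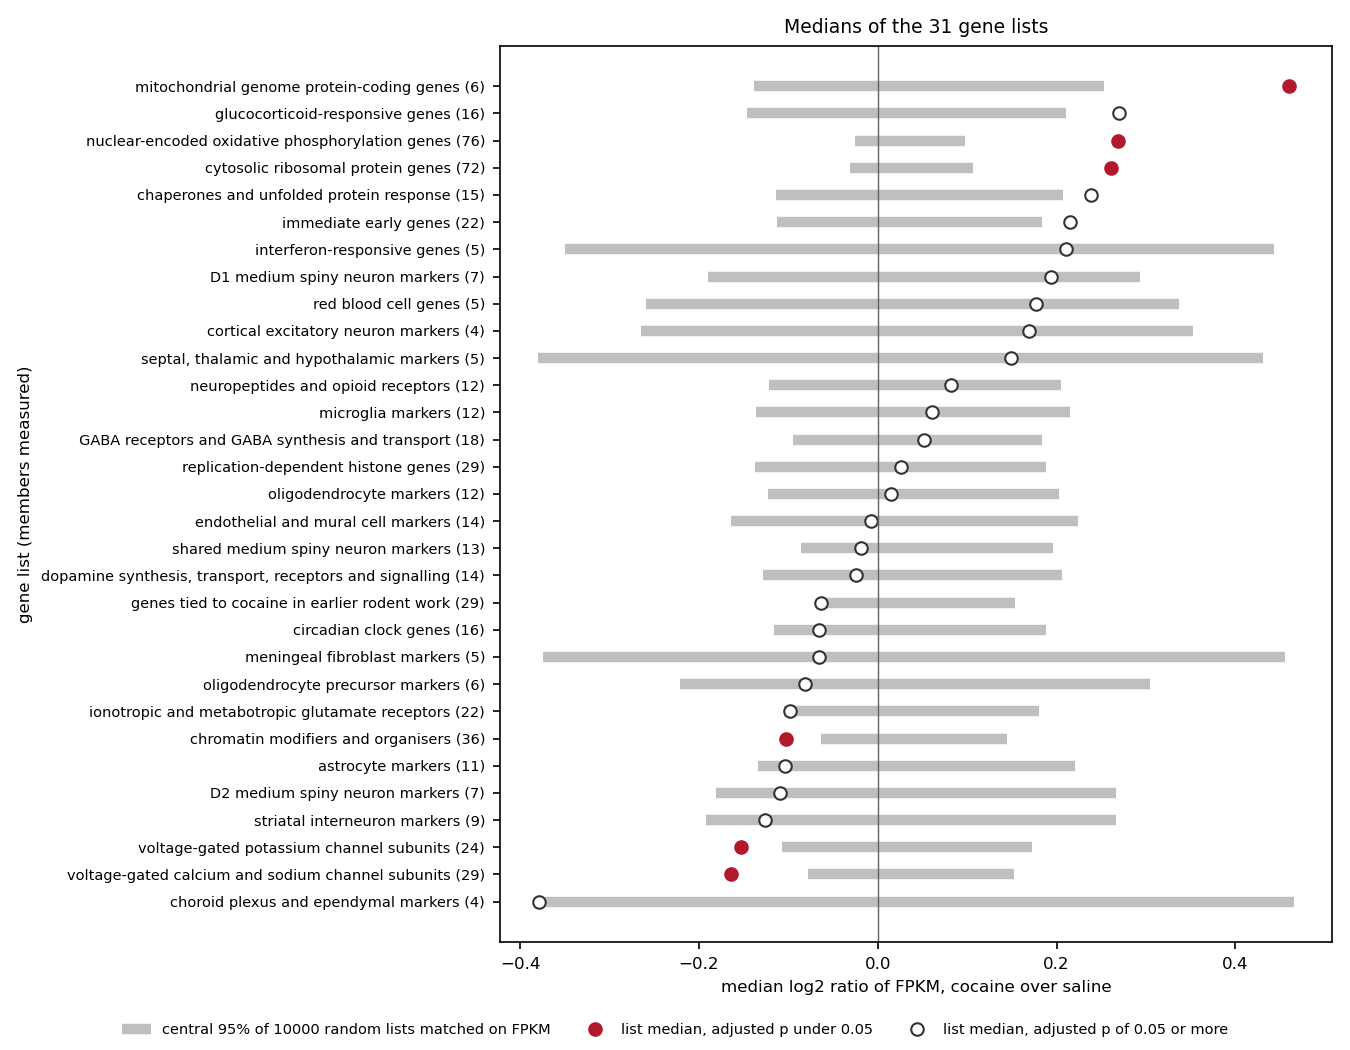
Median log2 ratio of FPKM (cocaine over saline) of the 31 gene lists, with the number of members measured beside each name. Grey bars are the central 95% of 10000 random lists matched on FPKM, and filled points are the 6 lists past 0.05 after adjustment, from 0.46 for the mitochondrial genome to -0.16 for calcium and sodium channels.

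Markers of cell types went both ways within most lists. Of 13 markers shared by medium spiny neurons, the main neurons of the striatum, 4 were called (5 when adjusted over the list alone), and among them Meis2 (-0.34), Pde10a (-0.30) and Ptpn5 (-0.25) fell in the authors' deposited table. Tac1 was the single call among 7 markers of D1 neurons (2 when adjusted over the list alone), and the 7 markers of D2 neurons held none (0 when adjusted over the list alone). Of 9 interneuron markers 2 were called (2 when adjusted over the list alone), Nos1 (-0.60) and Slc5a7 (0.54) in the authors' deposited table. Slc17a7, the glutamate transporter of cortical excitatory neurons, rose from 13.0 to 21.4 FPKM and was the single call among 4 markers of those cells (3 when adjusted over the list alone), by the authors' deposited table. Tcf7l2 (-1.03) was the single call among 5 septal, thalamic and hypothalamic markers (1 when adjusted over the list alone) in the authors' deposited table.

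Of 11 astrocyte markers 3 were called (3 when adjusted over the list alone): the glutamate transporter gene Slc1a2 fell from 426 to 258 FPKM, Sox9 fell (-0.60) and Fgfr3 rose (0.66) in the authors' deposited table. Of 12 oligodendrocyte markers 3 were called (4 when adjusted over the list alone), Mal (0.38), Cnp (-0.27) and Mbp (-0.08) in the authors' deposited table, and Cspg4 (-0.42) was the single call among 6 precursor markers (1 when adjusted over the list alone). Of 12 microglia markers 2 were called (2 when adjusted over the list alone), and among them Tmem119 rose (0.78) in the authors' deposited table. Endothelial Slco1a4 rose (0.80) and Pecam1 fell (-0.61) in the authors' deposited table, the 2 calls among 14 markers (3 when adjusted over the list alone). Of 4 choroid plexus and ependymal markers at 1 FPKM or more, Ttr alone was called (2 when adjusted over the list alone), and the list median was -0.38 at percentile 2.56. The 5 meningeal fibroblast markers held 0 calls (0 when adjusted over the list alone), and Alas2 (-1.31) was the single call among 5 red blood cell genes (2 when adjusted over the list alone) in the authors' deposited table. None of the cell-type lists had a median past the threshold after adjustment. The choroid plexus and ependymal list, which includes Ttr, passed with a minimum of 0.1 FPKM (median -1.15), with the mean in place of the median (-0.92) and with matching on length and GC content (percentile 0.13). It did not pass on FPKM + 1 (median -0.21), with the test statistic, or with matching on protein-coding length (percentile 1.18).

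Called genes differed in transcript length. The median length was 2532 nt for genes called higher, 5766.5 nt for genes called lower and 3017 nt for genes not called. Across 13658 genes, which are not independent replicates, Spearman's rho of the log2 ratio was -0.304 with transcript length and -0.193 with GC content. Among the 1366 genes with the shortest transcripts 147 were called higher and 18 lower, and among the 1365 with the longest 50 higher and 404 lower. The share of genes called also depended on level: it went from 3.84% in the lowest of 10 equal groups by FPKM to 29.7% in the highest, while the standard deviation of the log2 ratio went from 0.58 to 0.28 and the median implied standard error from 0.38 to 0.09. Treatment was given by cage, so cage and treatment cannot be told apart, and the table holds no pool values with which to check any gene.

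**Figure D3:**
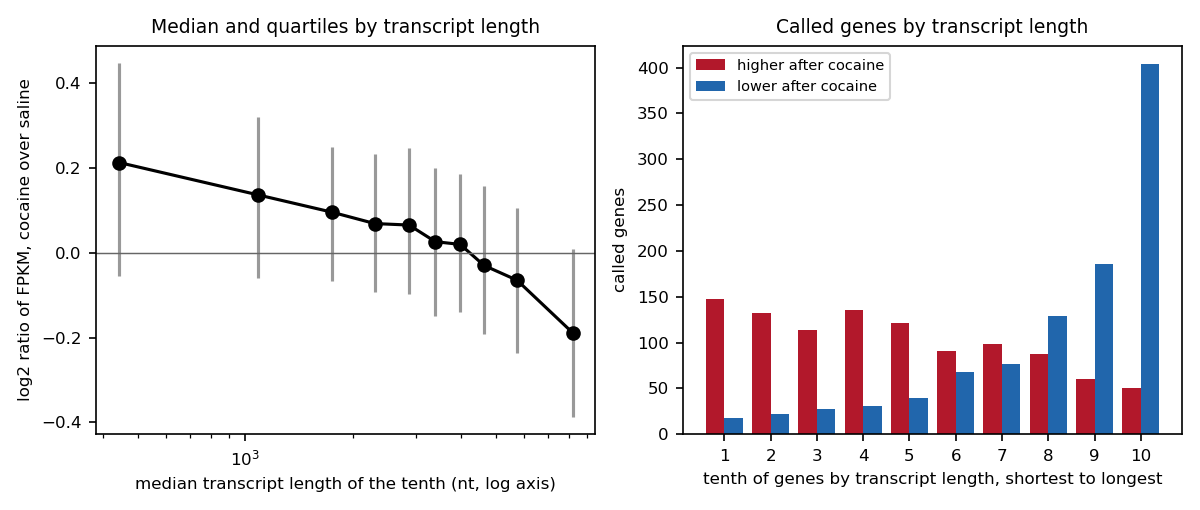
Left, median (points) and quartiles (lines) of the log2 ratio of FPKM, cocaine over saline, in 10 equal groups of 13658 genes by transcript length in nucleotides on a log axis. Right, number of genes called higher or lower in each group, from 147 higher and 18 lower in the shortest to 50 higher and 404 lower in the longest.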

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

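The settings that keep rows alone in their locus, keep genes above 0 in both groups, or match on transcript length and GC content were chosen only after the results were seen; the others were planned. The count of called genes stayed within 1.5 times of 2784 under 7 settings, from 1917 at a q under 0.01 to 3436 at a q under 0.1. It was 1266 when at least 1.5-fold was required and 1183 for rows alone in their locus, as both filters remove genes by construction. The 1266 include the 401 called genes with a group at 0, which were kept although no fold is given for them. The share higher was 50.8% with a minimum of 1 FPKM, 52.6% at a q under 0.1, unchanged with centring (a pseudocount of 1 cannot change it), and 55.6% for rows alone in their locus; the cause was not tested. The number of gene lists past the threshold was 6, between 4 and 9 under 7 settings (centring cannot change it), and 3 with rows alone in their locus (the mitochondrial and ribosomal lists, without the channel and chromatin lists); the cause was not tested. Of the lists lost there, the potassium channel median stayed at -0.15 and the chromatin median was -0.11, but the calcium and sodium channel median went from -0.16 to -0.08. The potassium channel and chromatin lists were also lost with a minimum of 0.1 or 5 FPKM, and the chromatin list with the mean in place of the median. The chromatin median was -0.10 and -0.11 with these minimums and its mean -0.09, while the potassium channel median went from -0.15 to -0.09 and -0.14. The choroid plexus, glucocorticoid, chaperone, glutamate receptor and immediate early gene lists passed only under some settings. Matching on length and GC content left 6 lists past the threshold, of which 2 were among the original 6 (oxidative phosphorylation and ribosomal protein genes), and matching on protein-coding length 5 lists, 2 of them among the original 6. Lists holding more calls than other genes numbered 5, and 6 or 7 under the planned settings. They numbered 2 for rows alone in their locus, and 1, the oxidative phosphorylation genes, against lists matched on length, GC content and FPKM. The cause was not tested. No list past the threshold changed sign under any setting run. When ratios were centred on the median of all genes (log2 0.04), no called gene among the 203 named changed sign, and of the uncalled ones Adcy5 alone moved by more than its error, from 0.02 to -0.01 in the authors' deposited table. No paired analysis was possible because the table gives 1 value per group and no value per pool, and for the same reason leaving out each pool, a pseudocount on pool values and other splits of the pools were not run. Unknown depth limits what an uncalled gene can show.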

Other observations

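The 14 gene families in the next paragraph, the second transcript length, the test on cell-type markers and both tests on genes with a group at 0 were chosen only after the result was seen; the tests on transcript length and genomic span were laid down after the list medians but before their own outcome was seen, and those on Ttr before theirs.

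Further families, which were picked with the pattern in view and so cannot test it, also differed. Of 39 proteasome subunit genes 12 were called, all 12 higher, with Psma3 (1.61) and Psme2 (1.17) leading by log2 ratio in the authors' deposited table, and their median of 0.22 lay at percentile 99.1 among lists matched on transcript length, GC content and FPKM. Of 28 ubiquitin-conjugating enzymes 7 were called, all higher, with Ube2w (1.10) and Ube2v2 (0.90) highest among the called members in the authors' deposited table, and 6 transfer RNA genes of the mitochondrial genome were called out of 12, 5 of them higher. Of 55 axon guidance ligands and receptors 19 were called, all 19 lower, with Sema6a (-1.03), Sema4c (-0.73), Sema5a (-0.63) and Plxna1 (-0.59) lowest in the authors' deposited table, and their median of -0.25 lay at percentile 0.01 among the matched lists. Protocadherins (median -0.22, 5 of 31 called, all lower) lay at percentile 0.02. Of 15 postsynaptic scaffold genes 8 were called, all lower, among them Dlgap2 (-0.70) and Shank1 (-0.56) in the authors' deposited table, and of 21 kinesins 8 were called, all lower, with Kif1b (-0.81) lowest, but these families lay at percentiles 18.8 and 44.0 of the matched lists, and at 1.98 and 17.3 with protein-coding length matched, so how far length accounts for the scaffold genes depends on the length used. Of the 14 families 13 passed the threshold with matching on FPKM and 8 with length and GC content matched as well.

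The rise of short-transcript lists and the fall of ion channel genes could come from a trend with transcript length and GC content, from cells of another type, or from the genomic span of genes. Against lists matched on length, GC content and FPKM the ribosomal protein genes lay at percentile 99.98 and the oxidative phosphorylation genes at percentile 100. Both also lay at percentile 100 with protein-coding length matched. Matched random lists already had medians of 0.14 by the longest transcript. Length and GC content as matched here therefore did not account for all of the rise of these lists. Finer bins and the lengths of the transcripts actually present were not tried, so the trend is not excluded. For the 53 ion channel genes it stays open: they lay at percentile 4.85 by the longest transcript, inside the central 95%, and at 0.99 by the median protein-coding transcript, outside it. Cells of another type cannot be excluded either, since the largest absolute median of 5 marker lists was 0.104 with random lists too wide to rule out 0.130, and for genes alone in their locus Spearman's partial rho of the log2 ratio was -0.0674 with locus span given transcript length and -0.164 the other way round, which leaves both open. A degradation or library difference between cages and an effect of cocaine on long neuronal transcripts both remain untested candidates.

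For the fall of Ttr by 3.30 on the log2 scale, a candidate explanation is choroid plexus tissue carried into the saline pools during dissection. The 7 other choroid plexus markers had a median log2 ratio of -1.31 on FPKM + 0.01, and Slc4a5 (0.312 to 0.0187 FPKM) and F5 (0.240 to 0.0910 FPKM) were called lower in the authors' deposited table, whereas Folr1, Kcnj13, Kl and Otx2 were lower without a call. Clic6, which was the most abundant of the 7, went the other way (4.22 to 5.49 FPKM) in the authors' deposited table, so not all markers follow. Reads divided among neighbours are excluded, because the largest FPKM gain of another gene of the locus was 0.0497% of the loss of Ttr. A change of Ttr within accumbens cells stays open as an effect of treatment that the group values cannot separate from dissection.

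Of 2784 called genes, 401 were listed at 0 in a group, 239 in saline and 162 in cocaine, at a median of 0.0547 FPKM in the other group. Among the 1000 status OK genes with exactly 1 group at 0, 46.4% of 862 that shared a locus were called against 0.725% of 138 that were alone (Fisher's exact test, two-sided, p = 1.88e-32). This is consistent with fragments being divided differently among overlapping rows in each group, and the called genes were not the more abundant ones (median 0.0547 FPKM, against 0.103 FPKM for those not called). Expression switched on or off by cocaine as the general cause would not by itself spare genes alone in their locus. Few of these were called (exact 95% interval of their share 0.0183% to 3.97%). However, in shared loci status OK was also given to rows at 0 in both groups, such as Klk10. Shared and lone rows need not have been tested on equal terms, so switching at such low levels is not excluded. The single gene alone in its locus was 2700081L22Rik, listed at 0 in saline and at 0.667 FPKM in cocaine in the authors' deposited table (q = 0.038).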
